A study of Solanum lycopersicum with 8 samples.

How the data were processed

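The measurement was messenger RNA abundance on the Affymetrix GeneChip Tomato Genome Array, a 1-colour array, in pericarp of tomato fruit at the breaker stage of ripening. The 8 arrays fell into 4 groups of 2, taken from the sample titles and source names: infected, wound control, ammonium and PBS control. Each array held a biological repeat that pooled 20 sites from at least 5 fruits, per the labels' protocols. The authors deposited log2 values, 1 for each of 10209 probe sets and each array. Per the submitters' processing notes RMA and Partek were used, with versions not given in the sources used here. RMA corrects the background, makes the distributions of the arrays equal and summarises the probes of a probe set, so a change of total messenger RNA per tissue does not show in these values. The lower and the upper quartiles of the 8 arrays each lay within 0.1 log2 of each other, with medians between 9.17 and 9.27. The values carry no detection call, so which probe sets lay at background is unknown, and no count of molecules or depth applies.

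The 108 probe sets for control transcripts were left out of the tests and read on their own, which left 10101. Gene names came from the platform annotation, which can be old: 909 probe sets had 1 gene symbol, none had several and 9192 had none. Of the 909, 885 were matched by gene identifier to the current RefSeq gene table (assembly SLM_r2.1), which gave 803 genes, 661 of them with a name. Where a gene had several probe sets (82 genes), that with the highest mean over all 8 arrays stood for it. No genome positions are given, since the probe sets were not mapped to a genome here.

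Each probe set was fitted with limma (version 3.58.1, R 4.3.3) as a linear model of the 4 groups over all 8 arrays, so that the groups shared 1 estimate of the spread, with 4 residual degrees of freedom and 3.03 prior degrees of freedom. Moderated statistics were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. The comparisons were infected against wound control, ammonium against PBS control, PBS control against wound control, and the difference of the first pair. Groups of 2 arrays allow 3 splits of 4 arrays, so no count of other splits was made.

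Before the data were examined, 22 gene lists, the tests, the alternatives and the rule for named genes were fixed. The rule named the 10 genes with the largest rise and the 10 with the largest fall for each main comparison among those past the threshold whose arrays did not overlap. It also named up to 4 members of each list with the smallest unadjusted p, and the 5 genes with the largest change each way in the other comparisons. List members were matched by symbol or alias alone, because the tables given hold no product descriptions, so the lists are short. Of the matches 5 were left out as names of another gene, 1 of them (LePIP1, an alias of an aquaporin) after list values had been seen. Lists were tested with limma's camera with a preset correlation of 0.01 between genes, on 1 probe set per gene among the 803 genes and with Benjamini-Hochberg adjustment over the 20 lists of at least 3 genes. Camera with an estimated correlation and fry were run beside it; fry asks whether a list moves on balance and does not compare it with other genes.

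The fit was tested on simulated data, with 200 of 10101 probe sets changed by known amounts. For the infection comparison it recovered 46% of changes of 0.5 log2, 86% of 1, 98% of 2 and 100% of 3, with 1.2% false calls. For the ammonium comparison it recovered 50%, 90%, 100% and 100%, with 5.03% false calls. Each simulated probe set had 1 spread for all 4 groups, and few probe sets changed. In the data the difference between the arrays of a group had an SD of 0.10 log2 for ammonium and 0.26 for infected. These rates may therefore not hold for the data. In a simulated list test the shifted list was called and none of 19 others. The simulated genes varied independently of each other, so this does not show how the list test behaves with correlated genes. The alternatives were other moderation, only the arrays compared, a filter on the lowest 25% of probe sets, quantile normalization, median centring, loess, other thresholds, averaged probe sets, the replicate number as a block, and each array left out in turn. Scaling to the control transcripts, their 3′ to 5′ gap or that of tomato transcripts as a covariate, and PBS control in place of wound control were added after seeing the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.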

Results

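Messenger RNA was measured in ripening tomato fruit (Solanum lycopersicum) on 8 Affymetrix GeneChip Tomato Genome arrays, in 4 groups of 2 arrays. The infected group held tissue colonised by Colletotrichum coccodes, a fungus that causes anthracnose rot of tomato fruit. Its control, the wound control, came from fruit that had a peel disc removed, 10 mm wide and 0.5 mm thick, and was sampled after 24 h. The hours after inoculation of the infected tissue are not given in the sources used here, so whether both were sampled at the same time is unknown. In the ammonium group the wounded site received 50 µl of 5 mM ammonium chloride in phosphate-buffered saline (PBS) every 4 h for 24 h, and in the PBS control it received the buffer alone. Each biological repeat pooled 20 sites from at least 5 fruits. The study asked which part of the response of the fruit to the fungus could be brought about by ammonium, which this fungus is known to release into host tissue. The number of arrays limits the precision of every value below. The ± values of group signals are SDs with n = 2, and those of log2 changes are standard errors (SE) from the fit over all 8 arrays.

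The 8 arrays separated by group. The first principal component held 70.8% of the variance and placed the infected arrays at −45.9 and −45.0, the ammonium arrays at −1.16 and 0.75, the PBS controls at 13.7 and 17.8, and the wound controls at 28.5 and 31.2. Arrays of 1 group correlated across probe sets at Pearson's r = 0.996 for infected, 0.996 for wound control, 0.998 for PBS control and 0.999 for ammonium, where probe sets are not independent replicates. The ammonium arrays lay closest together, with an SD of 0.10 log2 for the difference between them, against 0.26 for the infected arrays. On the infected arrays the 36 probe sets for poly-A control transcripts were higher than on the wound control arrays by a mean of 0.88 log2, and the 27 probe sets for hybridization controls by 0.45. The 2nd wound control array had the largest gap between 3′ and 5′ probe sets of the dap control, at 3.85 log2 against 2.10 to 2.87 on the other 7 arrays, and of actin, at 0.63 against at most 0.18. This gap, a sign of RNA quality, was also unequal between groups in transcripts of tomato itself. No test of that inequality was made, and the gap was used below as a covariate. For gapdh it was 0.03 and 0.20 on the infected arrays against 0.43 and 0.65 on the wound controls, and 0.19 and 0.14 on the ammonium arrays against 0.36 and 0.34 on the PBS controls. The mean gap of actin, gapdh and ef1a was 0.34 for infected, 0.69 for wound control, 0.23 for ammonium and 0.46 for PBS control.

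**Figure D1:**
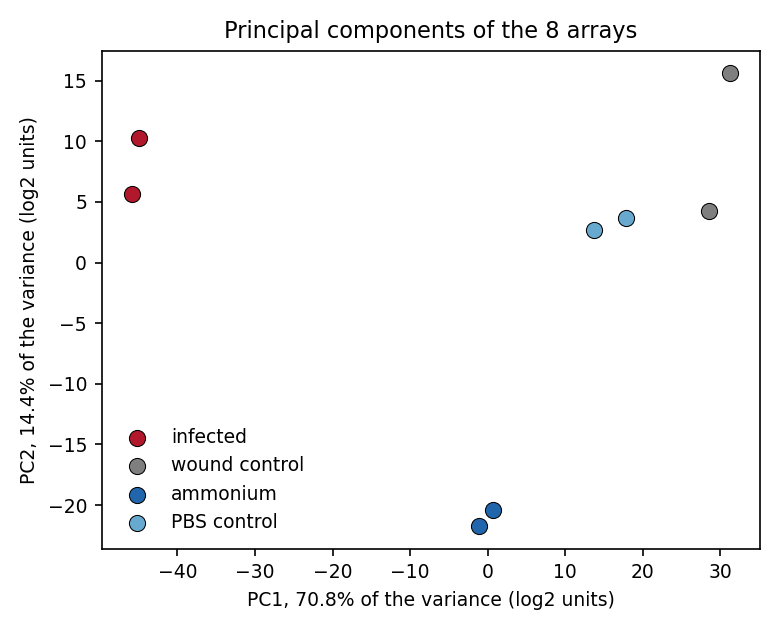
Scores of the 8 arrays on the first (x axis) and second (y axis) principal component of the log2 values of 10101 probe sets; each point is an array and the colours mark the 4 groups. The infected arrays sit at −45.9 and −45.0 on the x axis and the wound controls at 28.5 and 31.2, with the ammonium arrays between them and the PBS controls, at −21.7 and −20.4 on the y axis.

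Infected tissue was compared with wounded tissue to describe how the fruit responded to the fungus. Of 12 pathogenesis-related proteins 8 rose, and of 23 ripening genes 17 fell. The pectin methylesterase PMEU1 rose most among the named genes, from 7.96 ± 0.06 to 12.43 ± 0.37 log2, a 22.2-fold increase (SE of the log2 change 0.16). PR1b1 and P4, both pathogenesis-related proteins of family 1, rose 14.4-fold and 18.7-fold (3.85 and 4.23 log2, against 1.01 and 2.35 over the PBS control). The hydroxycinnamoyl transferase THT7-8, which makes phenolic amides, rose by 3.89 ± 0.22 log2 (SE). The ribonuclease RNALE fell 21.2-fold, from 12.16 ± 0.13 to 7.75 ± 0.37 log2, and the lipoxygenase LOX1.1 fell 18.2-fold. Of 10101 probe sets, 5095 passed limma's test at a Benjamini-Hochberg adjusted p under 0.05, 2327 of them higher and 2768 lower, and 1308 changed at least 2-fold. Among the 803 genes that could be identified, 201 rose and 262 fell.

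These counts are relative to the other probe sets of the same array. Scaling the arrays to the hybridization controls moved the median infection change by −0.45 log2, and scaling to the poly-A controls moved it by −0.88. With the hybridization scaling 7083 probe sets passed, 791 higher and 6292 lower, with the poly-A scaling 8882, 388 higher and 8494 lower, and with each array centred on its median 5294, 2981 higher and 2313 lower. Of the 79 named genes that passed in the infection comparison, 11 changed sign under the poly-A scaling, where NPR1, gad2 and PCNA passed as lower, and 3 under the hybridization scaling, none of them called. Of the 5095 calls 814 were turned to a call in the other direction by the poly-A scaling and none by the hybridization scaling. PBS control arrays in place of the wound control arrays left 3779 of the 5095 calls with the same direction and turned 11. Of the 79 named genes 74 kept their call that way and 17 moved by over 1.5 times, among them Prg1 (2.19 against 4.33 log2), CHI14 (0.75), LAPA1 (0.44), loxD (0.27) and ER5 (−2.84). The calls of CEVI57, PTI1, NPR1, THT1-3 and GABA-TP3 were lost. With the gap of the tomato transcripts as a covariate 75 of the 79 kept their call, not AMT1-2, gad2, GABA-TP3 and ARG2. In that fit 8 ethylene genes and 3 antioxidant genes fell, in place of 13 and 5, 2 wound and jasmonate-responsive proteins rose in place of 4, and 1 nitrogen gene rose and 1 fell in place of 2 and 2.

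Of 12 pathogenesis-related proteins, 8 rose and 1 fell (4 and 5 with the poly-A, 5 and 2 with the hybridization scaling), and 9 and 1 passed when adjusted over the list alone. The chitinases CHI3 and CHI14 rose by 2.27 ± 0.09 and 1.62 ± 0.15 log2 (SE), while the chitinase CHI17 fell by 1.52 on the log2 scale. PR1b1 has a further probe set, which differed by 0.14, and the P4 value rested on infected arrays that lay far apart (9.39 ± 1.55 log2). The list stood apart from the other genes in the camera test (limma adjusted p = 0.00765), a call lost with an estimated correlation (adjusted p = 0.47). Of 9 wound and jasmonate-responsive defence proteins 4 rose and 2 fell (2 and 6 with the poly-A, 2 and 4 with the hybridization scaling). They included the leucine aminopeptidase LAPA1, at 1.91 ± 0.13 log2, and CEVI57, which rose by 2.79 against the wound control but differed by −0.18 from the PBS control (limma adjusted p = 0.56).

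Among 7 genes of phenylpropanoid and phenolic amide synthesis 3 rose and 1 fell, and 5 and 1 passed when adjusted over the list alone. With the poly-A scaling 2 rose and 4 fell, with the hybridization scaling 3 and 2, and against the PBS control 2 and 2. The 3 that rose were the hydroxycinnamoyl transferases THT7-8, THT1-3 (1.85 ± 0.18 log2, and 0.53 over the PBS control, limma adjusted p = 0.0538) and THT7-1 (0.83 ± 0.10, which changed sign with the poly-A scaling). The chlorogenate synthesis gene hqt fell by 0.56. Of 12 defence transcription factors of the WRKY, ERF and NAC families 9 rose and 2 fell (2 and 6 with the poly-A and 2 and 3 with the hybridization scaling; 9 and 3 when adjusted over the list alone). The ethylene response factor EREB rose 14.3-fold and PTI5, a factor that interacts with the Pto resistance kinase, rose 4.47-fold. PTI5 was also 1 of the 4 that rose among 5 genes of the salicylate signalling list, NPR1, PTI1, PTI4, PTI5 and PTI6. PTI4, PTI5 and PTI6 were counted among the defence transcription factors too, so the count says little on salicylate itself. NPR1 rose by 0.33 log2 (0.11 over the PBS control, limma adjusted p = 0.22), and the kinase PTI1 fell by 0.78. In this list 1 rose and 3 fell with the poly-A scaling, and 1 and 1 with the hybridization scaling. Against the PBS control 2 rose and none fell, with PTI1 at −0.32 (limma adjusted p = 0.0518). The NADPH oxidase Wfi1, an enzyme of the oxidative burst, rose 5.21-fold and the peroxidase CEVI-1 rose 2.66-fold among 5 genes of their list, of which 3 fell with the poly-A scaling. RBOH1, the other NADPH oxidase measured, differed by 0.19 log2 (limma adjusted p = 0.33). Its signal was low, at 4.48 to 5.02 log2 over the 8 arrays, below the lower quartile of each. The CEVI-1 call was lost without the 2nd infected or the 1st wound control array, at 1.05 to 1.77 log2 over all arrays left out.

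Ethylene genes moved apart. The aminocyclopropane carboxylate synthases ACS1A and ACS6 rose 14.3-fold and 10.5-fold, while ACS4, a synthase of ripening fruit, fell 5.99-fold and the receptors ETR2 and ETR3 fell 4.01-fold and 2.65-fold. In all, 13 of 23 genes of ethylene synthesis and signalling fell and those 2 rose. The falls were 21 with the poly-A scaling, 19 with the hybridization scaling and 9 against the PBS control. Of 12 genes of jasmonate synthesis and signalling 4 rose and 5 fell (none and 8 with the poly-A scaling, 3 and 8 with the hybridization scaling). The lipoxygenase loxD, of jasmonate synthesis, was higher by 0.94 ± 0.08 log2 (not called with the poly-A scaling), and the jasmonate receptor COI1 fell by 0.67.

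Fruit ripening genes fell in 17 of 23 cases and rose in 2 (21 and 1 with the poly-A, 19 and 1 with the hybridization scaling), with PMEU1 among the risers. The MADS-box factor TDR4 fell 2.78-fold, and the carotenoid synthesis gene PDS, for phytoene desaturase, fell 2.99-fold. The camera test called this list lower (limma adjusted p = 0.00382), and the call was lost with an estimated correlation (adjusted p = 0.49). Of 22 genes of cell wall remodelling 13 fell and 6 rose (16 and 3 with the poly-A, 14 and 3 with the hybridization scaling). The cellulase Cel1 fell 15.5-fold with infected arrays far apart (7.47 ± 1.57 log2), and the galactosidase TBG3, the expansin exp9 and the mannanase Man4 had log2 changes of −3.80 ± 0.13, −3.46 ± 0.20 and −3.45 ± 0.21 (SE). Photosynthesis genes were lower in 3 of 8 cases (8 with the poly-A and 5 with the hybridization scaling), the photosystem II proteins PSBP (6.11-fold), PSBR (3.06-fold) and PSBO (2.87-fold). All 3 heat shock proteins of the list fell, by 0.77 log2 for HSP17-6, 2.08 for HSP21 and 0.90 for vis1, whose call was lost without either wound control array (−1.31 to −0.49). NCED1, the committed step of abscisic acid synthesis, fell 5.60-fold and was 1 of 3 of 7 abscisic acid and water stress genes that fell, with ER5 and AREB1 (all 7 with either control scaling).

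Glutamate dehydrogenase gdh1, which can bind ammonium into glutamate, rose 2.73-fold, and the ammonium transporter AMT1-2 was higher by 0.88 ± 0.26 log2, a call lost without either wound control array (0.44 to 1.31) and with both control scalings. They were the 2 that rose among 8 genes of ammonium and nitrogen assimilation, where 2 fell (1 rose and 6 fell with either control scaling). Antioxidant genes split into 3 that rose and 5 that fell of 13 (1 and 10 with the poly-A, 2 and 9 with the hybridization scaling), with the glutathione synthetase gene GSH2 up 3.41-fold and the superoxide dismutase FESOD down 2.28-fold. Of 12 proteases and cell death genes 6 rose and 2 fell (7 and 2 when adjusted over the list alone), led by the subtilase sbt3 at 5.21-fold (2.83-fold over the PBS control). The poly-A scaling gave 2 and 8, the hybridization scaling 3 and 5, and the PBS control 2 and 3. Glycolysis and fermentation genes rose in 5 of 11 cases and fell in 1 (1 and 7 with the poly-A, 2 and 6 with the hybridization scaling). In the sterol and terpenoid list 3 of 6 rose, among them HMGR of the mevalonate pathway by 1.22 log2 and the farnesyl diphosphate synthase FPPS1 by 0.60. The other was gad2, by 0.30, with a signal of only 5.08 to 5.54 log2 over the 8 arrays. The gene listed as gad2, like GABA-TP2, is in this list through a current alias from steroidal alkaloid synthesis, although the older names are those of GABA metabolism. The gad2 call was lost without either infected array, the 2nd wound control array or either ammonium array (0.20 to 0.39). With the poly-A scaling none of this list rose and 4 fell, and with the hybridization scaling 1 rose and 3 fell. Of 6 cell cycle genes and histones 2 rose and 1 fell (1 and 5 with the poly-A, 1 and 2 with the hybridization scaling). The 1 ribosomal protein gene, RPL8, differed by 0.15 log2 (limma adjusted p = 0.12) and by −0.73 with the poly-A scaling (limma adjusted p = 0.00108). None of 3 cuticle and epidermis genes and none of 2 seed genes passed, the markers here of other cell types, with differences from −0.50 to 0.06 log2. However, all 5 passed as lower with either control scaling, which lowered the infection change of every probe set. MAN2, MAN1 and TSW12 lay between 4.33 and 5.44 log2 on all 8 arrays and the cuticle gene ltpg1 between 5.61 and 6.26, below the lower quartile of every array. At such a signal they say little on other cell types. LE16, a lipid transfer protein of the cuticle list, differed from the PBS control by −1.60 log2 in infected tissue (limma adjusted p = 0.00345). For lists with no such count, adjustment over the list alone gave the same numbers, and camera called only the pathogenesis-related and ripening lists.

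**Figure D2:**
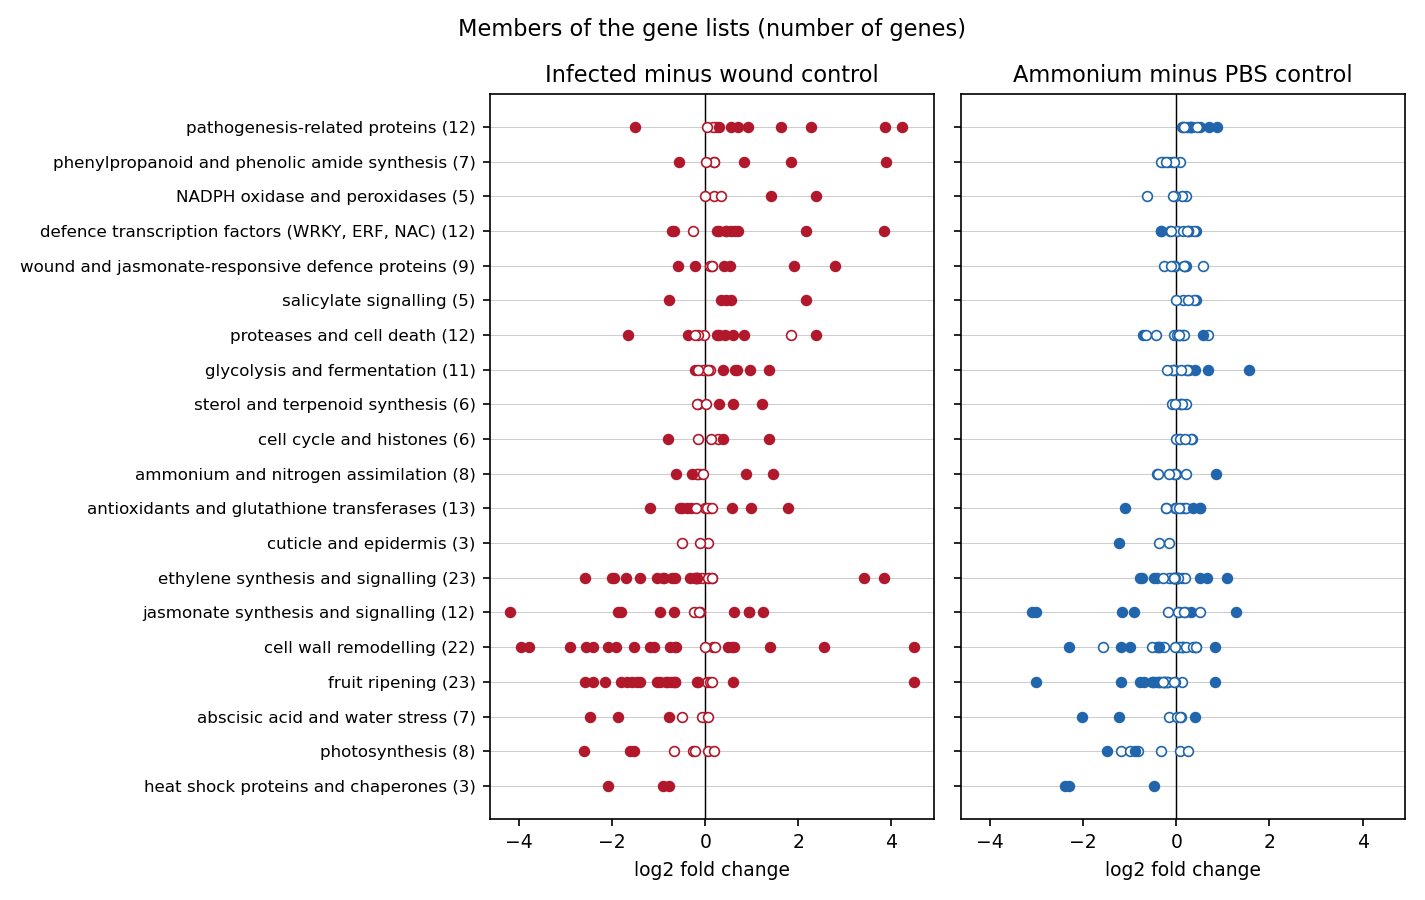
Log2 fold change (x axis) of each member of the 20 tested gene lists (rows, with the number of genes) in the infection comparison (left) and the ammonium comparison (right); filled points passed limma's adjusted p under 0.05. Among pathogenesis-related proteins 8 of 12 rose with infection (4 with the poly-A scaling) and 5 with ammonium (4 with that scaling), and among ripening genes 17 and 12 of 23 fell (21 and 2 with that scaling).

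Ammonium was compared with its buffer to find what ammonium alone changed in wounded fruit. Fewer genes passed than with infection, and the large changes were falls. The lipoxygenases LOX1.1 and loxC fell 8.51-fold and 8.08-fold, loxC from 9.18 ± 0.20 to 6.17 ± 0.20 log2. The mannanase Man4, the pectin methylesterase PME2.1 and the cellulase Cel2 fell 6.11-fold, 5.57-fold and 4.96-fold. The rises were smaller: a sucrose synthase listed as ssf rose 2.94-fold, the amino acid transporter AAP2 2.39-fold and the sucrose transporter SUT4 2.34-fold. Of 10101 probe sets 1525 passed (limma), 686 higher and 839 lower, and of the 195 that changed at least 2-fold 154 were lower. Of the 803 identified genes 67 rose and 97 fell.

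The count moved with the arrays used. Without the 1st or the 2nd ammonium array 187 and 296 probe sets passed, and without the 1st or the 2nd PBS control array 801 and 410. No moderation of the spread left 666, and a fit to the 4 arrays of this comparison alone gave 2868. With the poly-A scaling, which moved the median ammonium change by 0.24 log2, 891 were higher and 237 lower. Of the 50 named genes that passed here 19 kept their call without any 1 array, among them LOX1.1, loxC, Man4, PME2.1, Cel2, AAP2 and SUT4, and the other 31 lost it in at least 1 such fit with no change of sign. The call of ssf was lost without the 1st ammonium array, at 1.30 to 1.81 log2 over all arrays left out. With the gap of the tomato transcripts as a covariate 41 of the 50 kept their call, and opr2, CHI17 and GABA-TP3 were among the 9 that lost it. In that fit 3 pathogenesis-related proteins and 1 antioxidant gene rose in place of 5 and 3, 3 cell wall genes fell in place of 5, and no salicylate signalling gene, no protease and no rise of a defence transcription factor was called.

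Of 12 pathogenesis-related proteins 5 rose with ammonium and none fell (3 rose with the hybridization scaling and 4 with the poly-A scaling). CHI3 rose by 0.88 ± 0.09 log2 (SE) and PR-P2, of family 4, by 0.70 ± 0.07; both kept their calls without any 1 array. The call for PR-5 (0.51 ± 0.08) was lost without either ammonium array (0.43 to 0.58), and that for CHI17 (0.33 ± 0.07) without any 1 array of this comparison (0.31 to 0.34) and with both control scalings. Camera called the list higher (limma adjusted p = 0.00011), a call lost with an estimated correlation (adjusted p = 0.19). Ripening genes fell in 12 of 23 cases and rose in 1, against 17 and 1 when adjusted over the list alone, 6 and 1 with the hybridization scaling and 2 and 1 with the poly-A scaling. They included loxC, of fruit flavour volatiles, PDS at −0.77 ± 0.08 log2 and the acid invertase AI at −0.70 ± 0.09, not called without the 1st ammonium array (−0.78 to −0.62). The poly-A scaling ended the calls of PDS and AI. This list too was called lower (limma adjusted p = 1.37e-05), not with an estimated correlation (adjusted p = 0.44). The 3 heat shock proteins fell, HSP21 5.25-fold, vis1 4.91-fold and HSP17-6 1.40-fold (the last not called with the poly-A scaling or without either ammonium array or the 2nd PBS control array). Camera called them lower (limma adjusted p = 0.012), not with an estimated correlation (adjusted p = 0.52).

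Photosynthesis genes were lower in 2 of 8 cases (4 when adjusted over the list alone, and 4 with either control scaling), PSBP by 1.49 ± 0.18 and PSBR by 0.89 ± 0.08 log2. Of the 12 members of the jasmonate list 4 fell and 2 rose. LOX1.1, loxC, AOC (−1.17 ± 0.15) and AOS (−0.91 ± 0.11) fell, the last pair being the cyclase and synthase steps of jasmonate synthesis, and opr2, an oxophytodienoate reductase, rose by 1.28 ± 0.30. AOC and AOS lost their calls without the 1st ammonium array (−1.38 to −0.97 and −0.99 to −0.82 over all arrays left out), and opr2 without either ammonium array or the 2nd PBS control array (0.85 to 1.72 log2). In the cell wall list 5 of 22 fell and 1, PMEU1, rose by 0.83 ± 0.16 log2 (6 and 3 when adjusted over the list alone). With the poly-A scaling 4 fell and 4 rose, and with the hybridization scaling 3 and 1. PMEU1 lost its call without any 1 array of this comparison (0.75 to 0.91). Ethylene genes rose in 3 and fell in 3 of 23 cases (3 and none with the poly-A scaling), with the aminocyclopropane carboxylate oxidase ACO5 up 2.12-fold and the receptor ETR3 at −0.48 ± 0.07; these calls were lost without either ammonium array or the 2nd PBS control array (0.86 to 1.31 and −0.52 to −0.44 log2), that of ETR3 with both control scalings too. Antioxidant genes rose in 3 and fell in 1 of 13, where FESOD fell 2.14-fold.

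Glutamate dehydrogenase gdh1 rose 1.81-fold, from 12.36 ± 0.12 to 13.21 ± 0.02 log2, and was the 1 riser among 8 genes of ammonium and nitrogen assimilation, where GABA-TP3 fell by 0.41 (1 higher and 2 lower when adjusted over the list alone). Glycolysis and fermentation genes rose in 3 of 11 cases, ssf, the fructokinase FRK2 and the hexokinase hxk1 (6 rose and 1 fell when adjusted over the list alone). The calls of FRK2 and hxk1 were each lost without either ammonium array or the 2nd PBS control array, at 0.38 to 0.42 and 0.52 to 0.84 log2, and those of GABA-TP3 and PLDa1 without any 1 array of this comparison, at −0.45 to −0.36 and 0.37 to 0.44. The hybridization scaling ended the calls of FRK2, GABA-TP3 and PLDa1, and the poly-A scaling that of GABA-TP3. Of 7 abscisic acid and water stress genes ER5 fell 4.09-fold, LE16, a lipid transfer protein, fell 2.36-fold, and PLDa1 rose 1.32-fold. LE16 was also the 1 of 3 cuticle and epidermis genes that fell, and its call was lost without either ammonium array or the 2nd PBS control array (−1.59 to −0.89). The ammonium arrays held LE16 at 6.30 and 6.53 log2, overlapping the wound control arrays (6.63 and 6.48), so its fall rested on the PBS control. In the salicylate signalling list PTI4 was the 1 riser of 5 (3 when adjusted over the list alone, and 2 with the poly-A scaling). The same gene was the 1 riser of 12 defence transcription factors, where 1 fell. Those counts were 4 and 2 when adjusted over the list alone, and 2 and none with the poly-A scaling. Proteases gave 1 riser and 1 that fell of 12 (2 and 2 over the list alone, 2 and none with the poly-A scaling). No member passed among 9 wound and jasmonate-responsive proteins (1 rose with the poly-A scaling), 7 phenylpropanoid genes, 5 NADPH oxidase and peroxidase genes, 6 members of the sterol and terpenoid list, 6 cell cycle genes, 2 seed genes or the 1 ribosomal protein gene. With the hybridization scaling no salicylate signalling gene and no defence transcription factor passed. Wfi1 differed by 0.12 ± 0.13 log2 and THT7-8 by −0.32 ± 0.22.

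**Figure D3:**
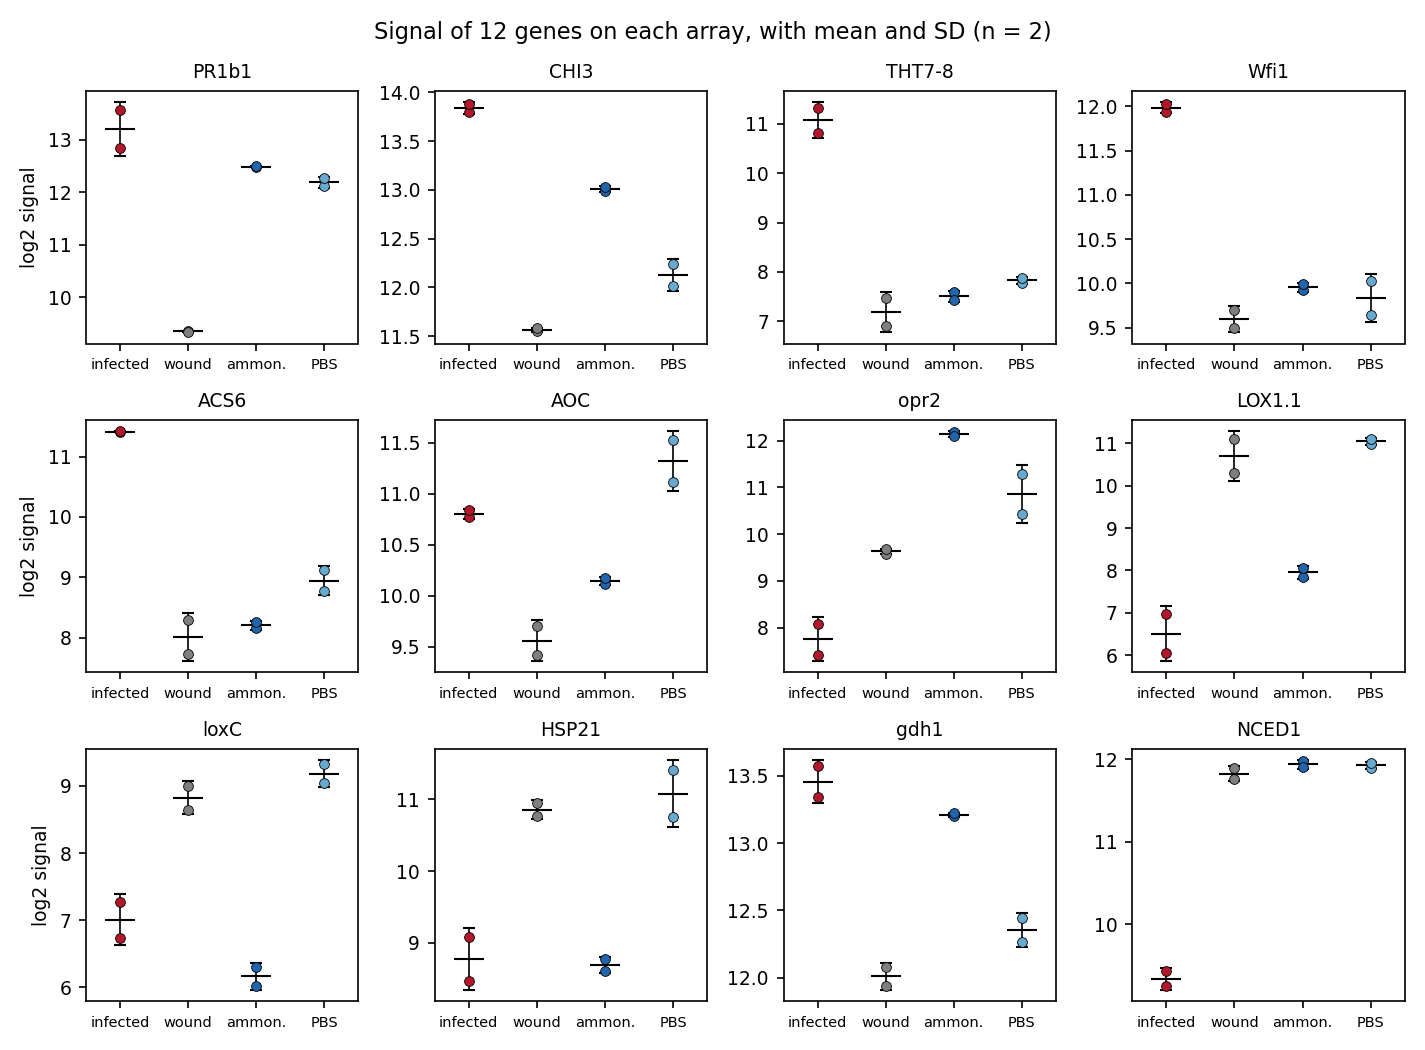
Log2 signal (y axis) of 12 genes on each array (points), with the group mean (horizontal line) and SD (bars, n = 2), in the infected, wound control, ammonium and PBS control groups. THT7-8 and Wfi1 are high on the infected arrays alone, LOX1.1 and loxC are low on the infected and ammonium arrays, and PR1b1 is lowest on the wound control arrays, at 9.35 against 12.19 on the PBS control arrays.

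The probe sets that changed with infection were then followed in the ammonium comparison, which used none of the same arrays. The 2327 that rose with infection were higher with ammonium by a mean of 0.15 log2, and 72.3% had the same sign, where 57.3% of the 5006 probe sets not called with infection were higher. The 2768 that fell had a mean change of −0.19 log2, and 68.0% had the same sign, where 42.7% of those not called were lower. Of the 686 that rose with ammonium 372 had also risen with infection and 70 had fallen, where independent lists would give 158 and 193. Of the 839 that fell with ammonium 615 had also fallen with infection and 101 had risen, against 230 and 188 for independent lists. The lists are not independent, since a probe set with a small shared spread tends to pass in both comparisons. The numbers for independent lists are therefore not chance values. A shared spread by itself favours neither direction, and the same-way counts were above the opposite ones. Camera found both sets shifted against the other probe sets (limma adjusted p = 2.97e-10 for the set that rose and 9.33e-16 for the set that fell), also with an estimated correlation (adjusted p = 0.0194 for each). Across the 10101 probe sets, which are not independent replicates, the effects correlated at Pearson's r = 0.43 and Spearman's rho = 0.40, and the ammonium change was 0.19 of the infection change by the slope of a line.

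**Figure D4:**
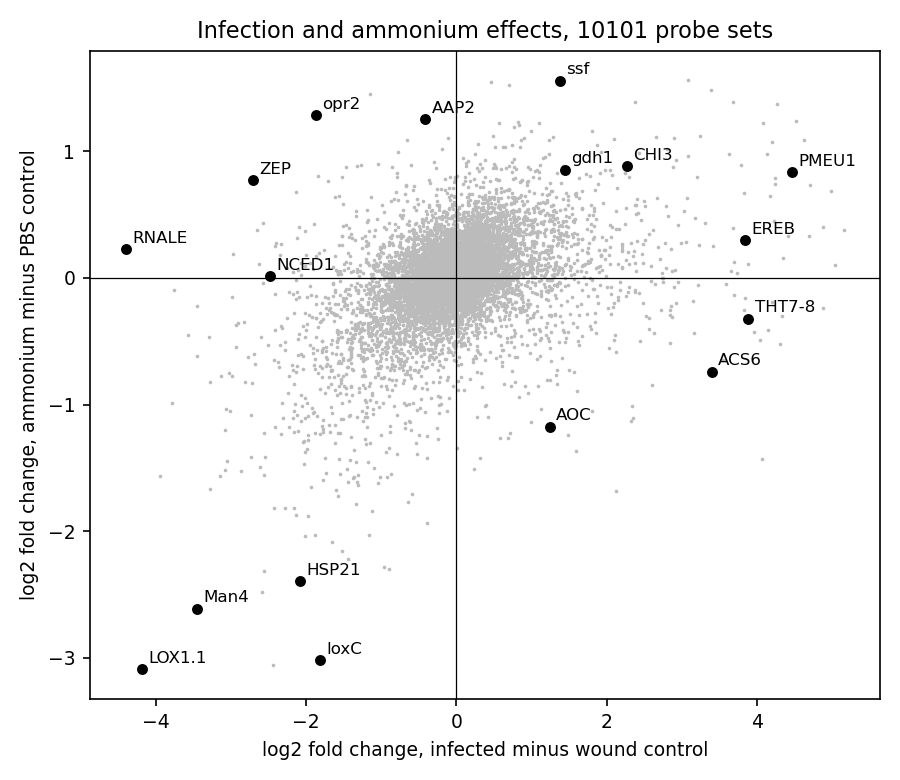
Log2 fold change with ammonium against PBS control (y axis) plotted over that with infection against wound control (x axis); each grey point is 1 of 10101 probe sets and black points carry gene names. The cloud runs from lower left, with LOX1.1 at −4.19 and −3.09, to upper right, with CHI3 at 2.27 and 0.88, while ACS6 and AOC lie at lower right and opr2 and ZEP at upper left.

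A test of the difference between the infection effect and the ammonium effect asked where they parted. It called 3032 probe sets (limma), 1253 with the infection effect above the ammonium effect and 1779 below. Prg1, THT7-8, ACS6, ODD and P4 had infection effects above the ammonium effects by 4.63 ± 0.39, 4.21 ± 0.31, 4.14 ± 0.26, 4.01 ± 0.85 and 3.78 ± 0.86 log2 (SE). RNALE, ZEP, exp9, opr2 and TomloxE had infection effects below them, with differences of −4.63 ± 0.24, −3.48 ± 0.22, −3.23 ± 0.29, −3.16 ± 0.42 and −3.01 ± 0.15. The difference holds the PBS control against the wound control as well: infected minus ammonium arrays gave 2.50 for Prg1 and 1.90 for P4 (limma adjusted p = 0.000718 and 0.0482). For PBS minus wound control the values were 2.13 and 1.87 (limma adjusted p = 0.0103 and 0.145), so that of P4 was not called. For the other 8 genes infected minus ammonium ran from −5.12 to 3.57. ZEP makes abscisic acid precursors and TomloxE is a lipoxygenase. The P4 difference lost its call without either ammonium array or the 2nd PBS control array (2.68 to 4.87 log2), and the count went to 1808 and 1685 without the 1st or the 2nd ammonium array. With the poly-A scaling 9090 probe sets passed, 232 of them above and 249 of the 3032 calls turned, and with the hybridization scaling 5122, 536 of them above. Centring each array on its median gave 1528 above and 1436 below, and loess gave 1513 and 1376. Camera called no gene list in this test (limma), with 3 at an unadjusted p under 0.05, against 12 called by fry, which asks only whether a list moves on balance.

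The PBS control was set against the wound control to see how far the repeated buffer drops, or the handling of these groups, moved the values. The drops and the handling cannot be told apart, because each group has its own arrays. RNA quality differed too, with a mean gap of tomato transcripts of 0.46 for PBS control and 0.69 for wound control. CEVI57 and PR1b1 were higher with PBS 7.82-fold and 7.16-fold, PR1b1 at 12.19 ± 0.11 against 9.35 ± 0.01 log2, while its further probe set differed by −0.02. Prg1 and the jasmonate cyclase AOC were higher 4.39-fold and 3.39-fold, and a gene listed as ctu2 4.49-fold. CBF1, a cold-response transcription factor, was lower 3.76-fold, and AO1, AAP2, ZEP and AgpL1 were lower, with log2 changes of −0.85, −0.82, −0.78 and −0.74. In all 424 probe sets passed (limma), 270 higher and 154 lower, and camera called no gene list, with 4 at an unadjusted p under 0.05, against 5 called by fry. The count was 721 and 143 without the 1st or the 2nd wound control array, 130 and 133 without the 1st or the 2nd PBS control array, and 145 without either ammonium array. It was 94 with the 3′ to 5′ gap of the control transcripts as a covariate, 269 with that of the tomato transcripts, 2233 with the poly-A scaling, 106 of them higher, and 427 with the hybridization scaling, 162 of them higher. The calls for AO1, AAP2, ZEP and AgpL1 were each lost without at least 4 of the 8 arrays, and that for Prg1 without the 2nd wound control or the 2nd PBS control array. AgpL1 had a low signal, at 4.61 to 5.59 log2 over the 8 arrays, below the lower quartile of each.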

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

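All tests in this part were chosen after the results had been seen, as no test of the control transcripts was planned. Groups of 2 arrays are too small for a search for outlying samples.

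Some probe sets outside the comparisons stood higher on both infected arrays than on every wound control and PBS control array. The poly-A control transcripts, which are added to the RNA before labelling, were 0.88 log2 above the wound control (lowest infected array 9.89, highest control array 9.71). The hybridization controls, which are added after labelling, were 0.45 log2 above it (10.48 against 10.35). The 17S rRNA probe set of tomato was 1.05 log2 above it (6.61 against 5.98). The 25S rRNA probe set did not part the arrays this way, at 11.53 and 10.42 on the infected arrays against 11.22 and 10.46 on the PBS control arrays.

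Weaker labelling toward the 5′ ends of transcripts does not account for the whole of the higher control transcripts. Their 12 probe sets at the 3′ ends alone were 0.55 log2 higher, with the lowest infected array at 10.79 and the highest wound control array at 10.41. A lower share of tomato messenger RNA in the labelled RNA, which RNA of the fungus could bring about, would raise both kinds of control against the tomato probe sets. The poly-A controls rose by 0.42 log2 more than the hybridization controls. A lower tomato share need not bring about this extra rise, so the extra rise cannot decide on that explanation. Different amounts of control mix may raise the controls too: the PBS control, with no fungus, was 0.40 log2 above the wound control in the poly-A controls. Neither can be told apart from the other, because each group has its own arrays and no RNA yields were given.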

How the results depend on the processing

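The infection count stayed within 1.5 times of 5095 under the trend, no moderation, its own arrays alone, the filter, quantile, median and loess normalization, averaged probe sets, the replicate block, adjusted p under 0.01 and each array left out (4244 to 4811). Of the 5095, 79.4% to 92.9% kept call and direction without 1 array, and none changed sign. A fold change of at least 2 left 1308, 195, 86 and 952 probe sets for infection, ammonium, PBS against wound control and the difference, and unadjusted p under 0.05 with that fold 1313, 209, 107 and 981. Adjusted p under 0.01 left 421, 99 and 1576 for the last 3. Those on adjusted p are stricter by construction, while unadjusted p with the fold admits some probe sets that failed the adjusted test; the cause of the other shifts was not tested. No moderation gave 666 for ammonium and 29 for PBS against wound control, and their own arrays alone 2868 and 148. Of the 5095 infection calls 74.1% were kept in direction and call with the arrays of that comparison alone. With the 3′ bias of the control transcripts as a covariate 63.4% were kept. Without 1 array the counts ran from 187 to 1850 (ammonium), from 130 to 721 (PBS against wound control) and from 1685 to 3029 (difference); a group left with 1 array is assumed to vary like the others. Scaling to hybridization controls gave 934 (ammonium) and 5122 (difference), and scaling to poly-A controls 8882 (infection), 2233 (PBS against wound control) and 9090 (difference). The 3′ bias covariate gave 2382 (ammonium) and 94 (PBS against wound control), and that from tomato transcripts 269 (PBS against wound control), with the others within 1.5 times. These scalings and covariates were chosen after seeing the data. The infection-called sets kept direction and call in the ammonium comparison under every alternative run for them, with r from 0.34 to 0.45. With an estimated correlation 0 lists were called for infection and 0 for ammonium, against 2 and 3 in the main test and 16 and 10 by fry, which tests another question (at unadjusted p under 0.05 with limma's estimated correlation, 1 and 1); no other alternative lost a list. Outside the control scalings, the covariates and the change of control, of 3866 values of named genes 3454 kept direction and side of the threshold, 339 lost and 59 gained a call, and 14 changed sign, none of them called. In the infection comparison these were TSW12 with quantile normalization (−0.0172) and MAN2 and MAN1 with median centring (0.0042 and 0.0652); with 1 array left out MAN1 ran from −0.124 to 0.0917 and ltpg1 from −0.306 to 0.095. In the ammonium comparison these were MAN1 with quantile and loess normalization (−0.0089 and −0.0034); with 1 array left out MAN1 ran from −0.0448 to 0.0593, MAN2 from −0.147 to 0.103 and Wfi1 from −0.0715 to 0.310. Whether same-numbered arrays were prepared together is not given in the sources used here. Their deviations correlated at −0.14 to 0.35 over the 6 pairs of groups, highest for infected with wound control, so a pairing there is not excluded. With the replicate block 5114, 1534, 444 and 3037 probe sets passed. Signal over background could not be read, since the values carry no detection call.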

Other observations

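Of the tests below, those of the 2nd wound control array, of the gap of tomato transcripts and of the PBS control in place of the wound control, and the scalings and arrays left out for the genes that crossed, were chosen after the results had been seen, while those of the replicate differences and of the small changes were written down before.

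Some genes moved one way with infection and the other way with ammonium; they were chosen for this after their values were seen. Of 661 named genes 123 passed in both comparisons (limma). Of these 33 rose in both, 68 fell in both, 7 rose with infection and fell with ammonium and 15 did the reverse. With the PBS control in place of the wound control 15 of these 22 kept both directions and both calls. The infection call turned for AOC and AAP2. AO1, AgpL1 and NHX1 changed sign with no call, and DREB3 and Rab1A lost the call. With the hybridization scaling 14 kept both and with the poly-A scaling 13, where ACS6, AOC and AOS lost a call and Rab1A was the 1 gene whose directions did not hold. Without 1 array no direction changed, but without the 1st or the 2nd ammonium array 1 and 3 of the 22 kept both calls, and without the 1st or the 2nd PBS control array 11 and 8. AOS, AOC and opr2, members of the jasmonate list, were among the 22. AOS rose by 0.95 log2 with infection and differed by −0.91 with ammonium, while opr2 fell by 1.88 with infection and rose by 1.28 with ammonium, and AOC went 1.24 and −1.17. The lipoxygenase TomloxE went −2.58 and 0.43. The choice of control matters for AOC, since infected arrays differed from the PBS control by −0.51 log2 (limma adjusted p = 0.0284). AOS stayed above that control by 0.52 (limma adjusted p = 0.00934) and opr2 below it, at −3.11 (limma adjusted p = 0.000258). The ammonium arrays held AOC at 10.12 and 10.17 log2, above the wound control arrays (9.70 and 9.42), so its fall rested on the PBS control. AOS (8.29 and 8.43 against 8.87 and 8.78) and opr2 (12.18 and 12.10 against 9.58 and 9.67) kept their ammonium directions against the wound control arrays.

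Further genes crossed in this way, and no gene group was tested for it. ACS6 rose by 3.40 log2 with infection and went −0.74 with ammonium, and ER24, a transcriptional coactivator known as MBF1, went 2.35 and −1.11. The small heat shock protein HSP17.4 went 1.48 and −1.24, apart from the 3 heat shock proteins of the fixed list, which fell in both. In the other direction the amino acid transporters AAP2 and AAP1 went −0.42 and −1.35 with infection and 1.25 and 0.30 with ammonium. ZEP went −2.71 and 0.77, and the ethylene-forming oxidase ACO5 went −0.65 and 1.09. For ZEP, ACS6, AO1 and AgpL1 the ammonium arrays overlapped the wound control arrays, so their ammonium directions rested on the PBS control. ZEP was at 9.85 and 9.95 log2 with ammonium and at 9.91 on both wound control arrays. AAP2 (12.02 and 12.03 against 11.53 and 11.64) and ACO5 (10.50 and 10.59 against 9.41 and 9.66) stayed above the wound control arrays. Against the PBS control AAP2 was higher in infected tissue, by 0.40 (limma adjusted p = 0.0394), so its direction with infection rested on the wound control.

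The ammonium effect ran in the direction of the infection effect across probe sets (r = 0.43), although the mean differences of the comparisons shared no array. The 3′ bias of the 2nd wound control array does not account for it, since r was 0.40 without that array. Whether the smaller 3′ to 5′ gap of tomato transcripts with both treatments accounts for it stays open. With that gap as a covariate r was 0.44 (0.39 to 0.65 without 1 array). That fit takes 1 slope per probe set for both comparisons. An error in the slope moves both effects the same way and can raise r by itself, so the fit cannot decide. A few probe sets with large changes do not account for the shared direction, since r was 0.34 among the 8719 that changed under 2-fold in both. Array to array variation along a single axis was tested with the replicate differences. The difference of the PBS control arrays correlated with the infection effect at −0.207 and that of the ammonium arrays at −0.176. Both lie in size below the bound of 0.215 set beforehand, which argues against this explanation. The larger lies below it by less than the 0.031 between them, so it is left open here. That margin was not part of what was written beforehand. A shared response of the fruit to ammonium and to the fungus, or a difference in ripening stage between the pools of fruit, may also lie behind it, and neither was tested.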
